A study of Mus musculus with 3 samples.

How the data were processed

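The data were droplet-based single-cell RNA libraries from whole mouse lung, taken 4 weeks after injury with bleomycin, a drug that damages the alveolar epithelium. The mice carried 2 inducible recombinases, CreER under the control of Scgb1a1 and DreER under the control of Sftpc, together with a dual fluorescent reporter in the Rosa26 locus. Lungs were digested with proteases and labelled cells were sorted by flow cytometry, per the labels' protocols. Red cells carrying tdTomato formed the Club-Tracer library, green cells carrying ZsGreen formed the AT2-Tracer library, and cells carrying both colours formed the BASC-Tracer library. There was 1 library for each lineage, so every comparison below is between libraries without replicates and no test between groups was possible.

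The deposited matrices held UMI counts (whole numbers of unique molecular identifiers per gene and cell barcode, not normalized), per the file headers, which name Cell Ranger. The submitters' processing notes give Cell Ranger 6.1.1 and genome build mm10. The annotation release that the authors used is not given in the sources used here. Each matrix listed 32287 features, of which 2 were the reporter transcripts ZsGFP and tdT. The libraries were made with 5′ gene expression chemistry, per the labels' protocols. The matrices held barcodes already called as cells, 5304 in the Club-Tracer library, 2439 in the BASC-Tracer library and 8884 in the AT2-Tracer library.

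Barcodes with fewer than 500 detected genes were left out (1872, 959 and 2686 barcodes in the Club-Tracer, BASC-Tracer and AT2-Tracer libraries), followed by barcodes with more than 15% mitochondrial UMIs (236, 78 and 339). Doublets were scored per library with Scrublet as implemented in scanpy, on barcodes with at most 25% mitochondrial UMIs. The automatic Scrublet threshold marked 0.0300% of Club-Tracer and 0.139% of BASC-Tracer barcodes, under the limit of 0.5% fixed for a working threshold. For these libraries the highest-scoring barcodes were taken out instead, at an expected share of 0.8% per 1000 barcodes (89 and 17 barcodes marked). In the AT2-Tracer library the automatic threshold marked 1.68% of barcodes and was used. Among barcodes past the other filters, 87, 17 and 101 were removed as doublets, leaving 3109, 1385 and 5758 cells, 10252 in all.

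The kept cells of all libraries were clustered together without batch integration, since integration would remove differences between groups that each consist of 1 library. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen without the reporter transcripts. Clustering used 30 principal components, 15 neighbours and the Leiden method at resolution 1, with seed 0, and gave 26 clusters. Marker lists for 17 cell types were fixed before the data were examined, as were the filters, the cluster settings, the alternative settings first listed below and the rule for named genes. The rule for turning markers into names was set after the clusters had been seen. A cluster was called X-like when X had at least 4 markers among the top 50 genes by fold, at least 2 times as many as the next list, and no other list had more in the top 10. Clusters that missed this rule stayed unnamed, and their shares are given. Calculations were done in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.

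Shares of cell classes are given with exact Clopper-Pearson 95% intervals. Counts summed over the cells of a class and library were expressed as CPM, the usual scaling by the total of all UMIs in the sum, with exact Poisson 95% intervals. Ratios of CPM carry exact conditional 95% intervals. All intervals and floors cover counting error only and say nothing about variation between animals. Those of CPM and of ratios leave out variation between cells as well. A count of 0 allows up to 3 counts. To compare shares of cells with a UMI across depths, each cell was thinned to 1500 UMIs and shallower cells were left out. Expression was compared within a class where both libraries held at least 50 cells of it. Genes at 50 CPM or more in either library were counted as apart when they differed by a factor of at least 2 on the scale log2((CPM + 5)/(CPM + 5)), which is a size and not a test. That scale understates differences of low genes.

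Within AT2-like cells the rule named the 10 genes with the highest and the 10 with the lowest log2 ratio among genes with at least 50 CPM and 30 UMIs in the higher library. Mitochondrial, ribosomal protein, hemoglobin, predicted, Rik, immunoglobulin, T cell receptor and sex-linked genes were left out of that ranking. In other classes 5 genes on each side were named. From each list with members at 50 CPM or more, up to 4 members were named, 2 at each end, and Scgb1a1 and Sftpc were always given. Genes listed as leading a cluster describe it and are not results. A list's median log2 ratio over members at a mean of 5 CPM or more was placed among 10000 random lists of the same size drawn within 20 bins of mean expression, as a description of these libraries. Beyond the marker lists there were 11 lists: MHC class II, interferon response, lipid synthesis, Notch, p53 targets, TGF-beta and YAP targets, immediate early and heat shock, acute phase and injury secretion, xenobiotic metabolism, lung transcription factors and sex-linked check genes.

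The ratio step was tested on simulated counts drawn from the AT2-like sums of each comparison, with 200 genes changed by known factors. In all 3 comparisons the 50 genes simulated at 0.25-fold, at 3-fold and at 4-fold each came out apart, and 0 of the 50 genes simulated at 1.5-fold did. The intervals held the true ratio for 190 of 200 genes in the comparisons of Club-Tracer and BASC-Tracer with AT2-Tracer, and for 192 of 200 between Club-Tracer and BASC-Tracer. The simulated counts were Poisson draws, the model behind the intervals. This checks the calculation only and not how counts vary between real cells. Gene positions come from the Gencode annotation of GRCm38, the assembly named mm10, matched by Ensembl identifier. All 128 named genes were placed, 127 of them under the same symbol, and positions are 1-based.

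The alternatives were mitochondrial limits of 10% and 25%, a minimum of 1000 genes, doublets kept, Leiden resolutions of 0.5 and 2, each library clustered alone, thinning to 3000 UMIs or none, pseudocounts of 1 and 20 CPM, gene limits of 20 and 100 CPM, scaling by the median ratio over genes, and the mean over cells of each cell's CPM. After the data had been seen, a looser naming rule (3 markers and no margin) and 3 subsets of AT2-like cells were added: cluster 0 alone, cluster 18 alone, and cells with 10000 UMIs or more. The ratio of each named gene was also taken without the cell of each library that held most of its UMIs, and that value is given where log2((CPM + 5)/(CPM + 5)) moved by more than a factor of 1.5. The added subsets needed only 30 cells per library, since cluster 0 held 43 AT2-Tracer cells.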

Results

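The libraries profile lung cells sorted for 3 genetic lineage labels 4 weeks after bleomycin. The Club-Tracer library was sorted for the label set through Scgb1a1, the secretoglobin of airway club cells. The AT2-Tracer library was sorted for the label set through Sftpc, the surfactant protein of alveolar type 2 (AT2) cells. The BASC-Tracer library was sorted for labels set through both genes, the expression pattern that defines bronchioalveolar stem cells at the junction of airway and alveolus. Descent of the sorted cells was not tested. Deposited UMI counts came to 62570890, 29013077 and 72256580 in the Club-Tracer, BASC-Tracer and AT2-Tracer libraries. After filtering they held 3109, 1385 and 5758 cells with medians of 15336, 15145 and 9565.5 UMIs and 3639, 3899 and 2862 genes per cell. There are no replicates, so differences between libraries have no replicate check.

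The driver genes and reporters were examined first, to check the library labels. Scgb1a1 (ENSMUSG00000024653, a protein-coding gene on the reverse strand of chromosome 19, 9083636 to 9087958) stood at 179359 CPM in the Club-Tracer library, 80963 in the BASC-Tracer library and 1172 in the AT2-Tracer library. Sftpc (ENSMUSG00000022097, protein-coding, reverse strand of chromosome 14, 70520949 to 70524081) ran the opposite way, at 15791, 29883 and 42964 CPM. The green reporter ZsGFP stood at 26.5 CPM (95% interval 25.2 to 27.8) in the red-sorted Club-Tracer library, 8085 in the BASC-Tracer library and 5863 in the AT2-Tracer library. The red reporter tdT stood at 619 CPM, 1181 CPM and 0.936 CPM (0.719 to 1.20). Cyp2f2, an airway cytochrome P450, was highest in the Club-Tracer library at 4046 CPM, against 2342 and 31.2 CPM. The basal keratin Krt5 was at 43.7, 5.79 and 0.193 CPM, and Foxj1, the master regulator of motile cilia, at 134, 63.9 and 4.98 CPM. The leukocyte gene Ptprc ran from 4.45 and 22.2 CPM to 98.8 CPM in the AT2-Tracer library. The Y-linked genes Ddx3y (31.9, 49.1 and 54.8 CPM) and Eif2s3y (46.8, 61.7 and 60.3 CPM) were present in each library, and Xist stood at 0.274, 0.692 and 0.490 CPM.

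**Figure D1:**
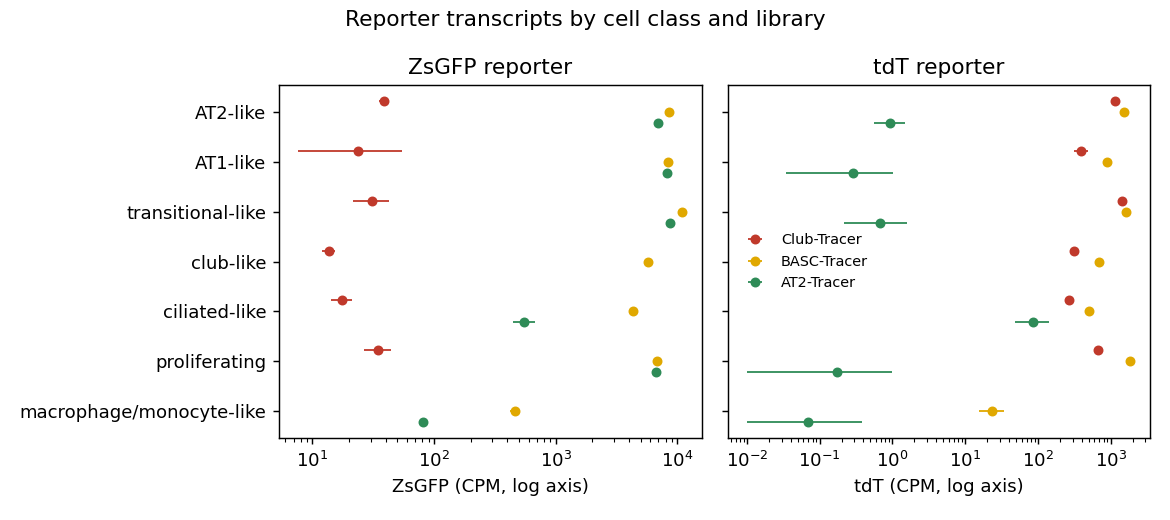
Levels of the reporter transcripts ZsGFP and tdT (CPM, log axes) in cell classes of the 3 libraries, with points for summed counts and bars for exact Poisson 95% intervals. ZsGFP in AT2-like cells stood at 38.8 CPM in the Club-Tracer library, 8478 in the BASC-Tracer library and 6987 in the AT2-Tracer library, and tdT at 1147, 1540 and 0.942 CPM.

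The first comparison asked which cell classes each sorted library held. AT2-like cells, the surfactant-secreting class, made up 12.7% (11.6 to 13.9) of Club-Tracer cells, 18.1% (16.1 to 20.3) of BASC-Tracer cells and 19.1% (18.1 to 20.1) of AT2-Tracer cells. AT1-like cells, the flat gas-exchange class, made up 1.48% (1.09 to 1.97), 7.94% (6.57 to 9.49) and 16.3% (15.4 to 17.3). Transitional-like cells, led by Clu, Tpm2 and Cldn4 and rich in Krt8, the keratin of injury-associated intermediates, made up 1.80% (1.36 to 2.33), 3.03% (2.19 to 4.08) and 6.30% (5.69 to 6.96). Airway classes ran the other way. Club-like cells made up 27.7% (26.1 to 29.3), 12.1% (10.5 to 13.97) and 0.104% (0.0382 to 0.227), and ciliated-like cells 15.3%, 5.63% and 0.278%. Basal-like cells made up 7.59%, 0.505% and 0.0347%. Proliferating cells made up 1.74%, 2.89% and 3.94%.

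Cells outside the epithelium differed between the sorts as well. Macrophage or monocyte-like cells made up 0.257% of Club-Tracer, 7.58% of BASC-Tracer and 29.0% of AT2-Tracer cells. Endothelial-like cells made up 3.09%, 11.1% and 0.226%, and fibroblast or smooth muscle-like cells 0.0965%, 0.289% and 0.590%. Epithelial clusters held 94.6%, 77.5% and 67.7% of kept cells. Unnamed and proliferating clusters counted as epithelial when Epcam stood above Ptprc and Pecam1, and other clusters by their class. By this rule cluster 24, with Epcam and Ptprc both at 88.5 CPM, was left out. Cluster 25, with Epcam at 220 and Ptprc at 108 CPM and Cd79a among its leading genes, was counted as epithelial. Of epithelial cells alone, AT2-like cells were 13.4%, 23.4% and 28.2%, AT1-like cells 1.56%, 10.2% and 24.1%, and club-like cells 29.2%, 15.6% and 0.154%. The sort gates, cell recovery and the lower depth of the AT2-Tracer library can each set these shares. A share does not show descent either. In the Club-Tracer library tdT was seen in 45.7% of AT1-like and 45.8% of endothelial-like cells (medians of 3229 and 1298 UMIs). Those AT1-like cells are thus not shown to carry the label above background. The tdT shares of AT2-like (95.9%), transitional-like (92.9%), basal-like (92.4%), club-like (69.7%) and ciliated-like cells (63.7%) were higher. These cells were also deeper, with medians from 10274 to 26179 UMIs. In CPM, tdT stood at 1147, 1434, 783, 316 and 267 in these classes, against 390 in AT1-like and 482 in endothelial-like cells. By CPM, club-like and ciliated-like cells are thus not shown to carry the label above background.

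The naming rule kept 28.2%, 30.8% and 24.1% of cells of the Club-Tracer, BASC-Tracer and AT2-Tracer libraries unnamed. Cluster 17, led by Sprr1a, Cdkn1a, Ccng1 and Phlda3, held 1.29%, 10.6% and 11.3%. Cluster 10, led by Chia1, Krtap17-1, Ces1g and Ly6a, held 8.85%, 4.98% and 0.0868%. Cluster 14, led by the airway secretory genes Scgb3a1, Bpifa1, Reg3g and Bpifb1, held 7.24%, 0.650% and 0.0174%. Cluster 12, led by Tpm2, S100a6 and Sparc, held 1.80%, 2.67% and 4.32%. Cluster 7, low in UMIs and led by Malat1 and Lars2, held 3.38%, 5.34% and 2.69%. Cluster 2 held 3.73%, 2.82% and 0.0174%, and cluster 24 0%, 2.02% and 0%. Cluster 25, with few UMIs per cell and led by Lars2, S100a4 and Cd79a, held 0%, 0.217% and 3.21%. Immune cells were in cluster 11, led by MHC class II genes (1.09%, 0.722% and 1.75%), cluster 5, led by T cell genes (0.836%, 0.650% and 0.0868%), and cluster 3, proliferating cells with macrophage genes (0.0322%, 0.0722% and 0.590%). A cluster filled mostly by 1 library may reflect that library and not a cell type.

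Several shares moved by more than 1.5 times with the settings. The transitional-like share ran from 1.78% to 11.9% in the Club-Tracer library, from 3.03% to 18.6% in the BASC-Tracer library and from 6.30% to 21.99% in the AT2-Tracer library. The AT1-like share ran from 1.33% to 6.95% and from 4.91% to 14.1% in the Club-Tracer and BASC-Tracer libraries. The club-like share of the AT2-Tracer library reached 8.13% when each library was clustered alone, and the basal-like class was lost at resolution 0.5. The macrophage or monocyte-like share of the AT2-Tracer library ran from 28.7% to 31.0%, and that of the Club-Tracer library from 0.179% to 1.38%. The order of the libraries changed too. With each library clustered alone, the Club-Tracer library stood above the BASC-Tracer library for AT1-like (6.95% against 4.91%), transitional-like (4.76% against 3.03%) and AT2-like cells (15.1% against 14.2%). The BASC-Tracer library stood above the AT2-Tracer library for transitional-like cells under the looser naming rule (18.6% against 17.7%), and for AT2-like cells with mitochondrial limits of 10% (18.5% against 16.8%) and 25% (14.9% against 14.3%).

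**Figure D2:**
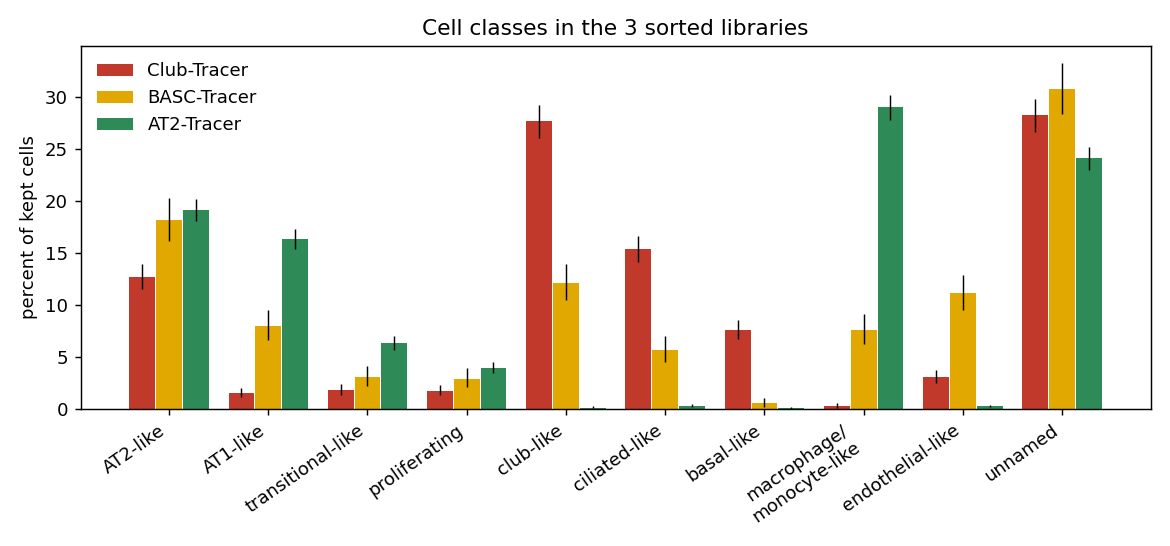
Share of kept cells (percent) in each cell class for the Club-Tracer, BASC-Tracer and AT2-Tracer libraries, with bars for shares and lines for exact binomial 95% intervals. AT1-like cells made up 1.48%, 7.94% and 16.3%, club-like cells 27.7%, 12.1% and 0.104%, and macrophage or monocyte-like cells 0.257%, 7.58% and 29.0%.

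A readout without clusters counted cells with a UMI of marker genes after thinning to 1500 UMIs, which left out 154, 146 and 427 shallower cells. Sftpc was seen in 41.4% (39.6 to 43.2), 59.6% (56.8 to 62.3) and 76.0% (74.8 to 77.1) of Club-Tracer, BASC-Tracer and AT2-Tracer cells, and Scgb1a1 in 97.6%, 77.6% and 6.32%. Both genes were seen in 40.6%, 46.0% and 5.44%. Ager, a receptor of AT1 cells, was seen in 38.5%, 52.3% and 55.1%, and Krt8 in 58.2%, 50.8% and 42.1%. Without thinning, Sftpc was seen in 85.3%, 90.8% and 98.3% of cells, Scgb1a1 in 100.0%, 99.4% and 20.6%, both in 85.3%, 90.4% and 20.4%, Ager in 67.4%, 76.9% and 71.1%, and Krt8 in 87.4%, 79.1% and 62.3%.

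Free RNA limits this readout. In immune and endothelial-like cells, which should lack these genes, the thinned shares were 88.1%, 60.5% and 58.3% for Sftpc, 100.0%, 77.0% and 4.87% for Scgb1a1, and 88.1%, 55.3% and 3.82% for both. For Ager they were 61.9%, 32.2% and 5.85%, and for Krt8 52.4%, 27.6% and 2.09%. These background cells were shallower, with medians of 1931, 4574 and 8101 UMIs before thinning against 16160, 17738 and 10299 for all cells. In the Club-Tracer library the shares of Sftpc, Scgb1a1, Ager and of Sftpc with Scgb1a1 lay at or below background, and they are not read as expression. In the BASC-Tracer library the Sftpc share and the joint share lay below background and the Scgb1a1 share was close to it.

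AT2-like cells of the Club-Tracer and AT2-Tracer libraries were compared next, 395 Club-Tracer cells (median 26179 UMIs) against 1100 AT2-Tracer cells (17013). Genes of the airway club program were higher in the Club-Tracer cells. Scgb1a1 was 1475-fold higher (1384 to 1575), at 72174 against 48.9 CPM. Free RNA of these genes was abundant: the median Club-Tracer AT2-like cell held 346 UMIs of Scgb1a1, 1 of Scgb3a2, 11 of Cyp2f2 and 2 of Retnla, against 239.5, 10, 7 and 7 in the median endothelial-like cell of that library, which held fewer UMIs in all (1298). The Scgb3a2 and Retnla levels of the median cell are therefore not read as expression. Scgb3a2, a second secretoglobin (protein-coding, forward strand of chromosome 18, 43764289 to 43767399), was 853-fold higher (532 to 1464), and Cyp2f2 (forward strand of chromosome 7, 27119909 to 27133660) 136-fold higher (114 to 163). The tight junction gene Cldn10 was 96.1-fold higher (61.9 to 158), and Cckar, the cholecystokinin A receptor, was at 1108 UMIs against 1, a ratio of 2041 (366 to 80686). Retnla, a secreted resistin-like factor of type 2 inflammation (forward strand of chromosome 16, 48842551 to 48844461), stood at 3626 against 225 CPM, and its neighbour Retnlg, a neutrophil marker, at 83.6 against 5.28 CPM. Cd24a was 33.7-fold, Plpp3 29.1-fold and the flavin monooxygenase Fmo2 24.9-fold higher. Cldn10, Cckar, Cd24a, Plpp3 and Fmo2 were not set against the background of endothelial-like cells.

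On the other side stood a secreted inhibitor, an apolipoprotein and an alarmin. Itih4, an acute phase inhibitor (protein-coding, forward strand of chromosome 14, 30886476 to 30902353), was 67.6-fold higher (45.7 to 105) in the AT2-Tracer cells. The apolipoprotein Apoe (reverse strand of chromosome 7, 19696109 to 19699188) was 30.6-fold higher there (23.1 to 41.3), and the alarmin Il33 (forward strand of chromosome 19, 29925114 to 29960718) 9.68-fold higher (8.59 to 10.9). The median cell held 0 (Club-Tracer) and 1 (AT2-Tracer) UMIs of Apoe, against 51 in AT2-Tracer macrophage or monocyte-like cells. Macrophage RNA as its source stays open. Bex4 (40.1-fold), Gpc3 (22.6-fold), Bicc1 (13.96-fold), Mme (13.04-fold), Sgpp2 (12.7-fold), Steap2 (11.6-fold) and Acoxl (9.94-fold) were also higher in the AT2-Tracer cells. Sftpc differed little, at 74994 against 104100 CPM, a log2 ratio of -0.47.

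The fixed lists give the same comparison by gene group. The club list had a median log2 ratio of 2.99, above 100.0% of matched random lists, and 10 of its 12 members at 50 CPM or more were 2-fold higher in the Club-Tracer cells, with Ces1d (0.72) and Gsta4 (0.98) closest to even. The xenobiotic metabolism list stood at 1.56 (percentile 100), with 8 of 11 members 2-fold higher, while Cyp2b10 (-0.12) and Por (0.77) were not. It shares Cyp2f2, Gsta3, Gsta4, Aldh1a1 and Cbr2 with the club list, so these results are not separate. Free RNA, abundant for Scgb1a1, Scgb3a2 and Cyp2f2 in the Club-Tracer library, can raise both lists. Their medians and percentiles are therefore not read as expression by AT2-like cells alone. The MHC class II list, the genes that present antigen to helper T cells, stood at -1.47 (percentile 0), and all 6 members at 50 CPM or more were 2-fold lower, among them H2-Ab1 (-1.90), H2-Eb1 (-1.64), H2-DMb1 (-1.44) and H2-DMa (-1.27). The AT1 list stood at -1.08 (percentile 0), with 5 of 9 members 2-fold lower, from Akap5 (-2.09) and Col4a4 (-2.02) to Hopx (-0.11) and Gprc5a (-0.01). The AT2 list stood at -0.41 (percentile 0.04), with 5 of 18 members 2-fold lower, led by Fabp5 (-2.46) and Hc (-2.25), while Cxcl15 (0.42) and Lyz2 (0.83) were higher. The TGF-beta and YAP target list stood at -0.78 (percentile 0.04) with no member of 4 past 2-fold, from Ccn1 (-0.91) and Col4a1 (-0.85) to Amotl2 (-0.73) and Thbs1 (0.24).

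Of the remaining lists in this comparison, Notch stood at 0.51 (Hes1 0.74), immediate early and heat shock at 0.17 (Nr4a1 -0.98, Dusp1 -0.55, Hspa1a 0.85, Hspa1b 0.96), and lung transcription factors at 0.14 (Id2 -1.02, Etv5 -0.78, Klf5 0.27, Elf3 0.36). Acute phase and injury secretion stood at 0.06, with Lrg1 (-1.23) and Il33 2-fold lower and Cp (2.67) and Retnla (3.98) 2-fold higher. Lipid synthesis stood at 0.02 (Fasn -0.53, Acsl4 -0.18, Idi1 0.15, Insig1 0.55), p53 targets at -0.05 (Ccng1 -0.29, Bax -0.11, Cdkn1a -0.05) and transitional at -0.07 (Hbegf -0.99, Lgals3 -0.99, Clu 0.88, Nupr1 1.38). Interferon response stood at -0.22 (Ifitm3 2.32), sex-linked check genes at -0.24 (Ddx3y -0.42, Eif2s3y -0.13), ciliated at -0.63 (Sec14l3 -0.51) and macrophage or monocyte at -0.96. The goblet, basal, neuroendocrine, tuft, proliferating, neutrophil, lymphocyte, endothelial, fibroblast or smooth muscle, mesothelial and erythroid lists had fewer than 3 measured members and no median.

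Of 2863 genes at 50 CPM or more, 204 were at least 2-fold apart, 75 higher in the Club-Tracer and 129 higher in the AT2-Tracer cells. The median gene lay at -0.14, and scaling by the median ratio gave 182 genes, 89 and 93. The classes sat in different clusters. Cluster 0, led by Lyz1 and Cxcl15, held 98.2% of the Club-Tracer AT2-like cells and 3.91% of the AT2-Tracer ones. Cluster 18, with Hc, Il33, Lrg1, Itih4 and Lcn2 among its leading genes, held 1.77% and 96.1%. The clusters were built from expression, so ratios of these genes within a cluster are shaped by that choice of cells. Within cluster 0 alone (388 and 43 cells) 123 genes were apart, the AT1 list stood at -0.37, the AT2 list at -0.14, xenobiotic metabolism at 1.03 and MHC class II at -1.51, and the Club-Tracer to AT2-Tracer ratio was 0.331 for Apoe, 0.132 for Itih4, 13.8 for Cyp2f2, 0.388 for Il33, 0.400 for Hc and 1.01 for Lrg1. Gene limits of 20 and 100 CPM gave 339 and 113 genes, and a pseudocount of 20 CPM put the club list at 1.73.

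**Figure D3:**
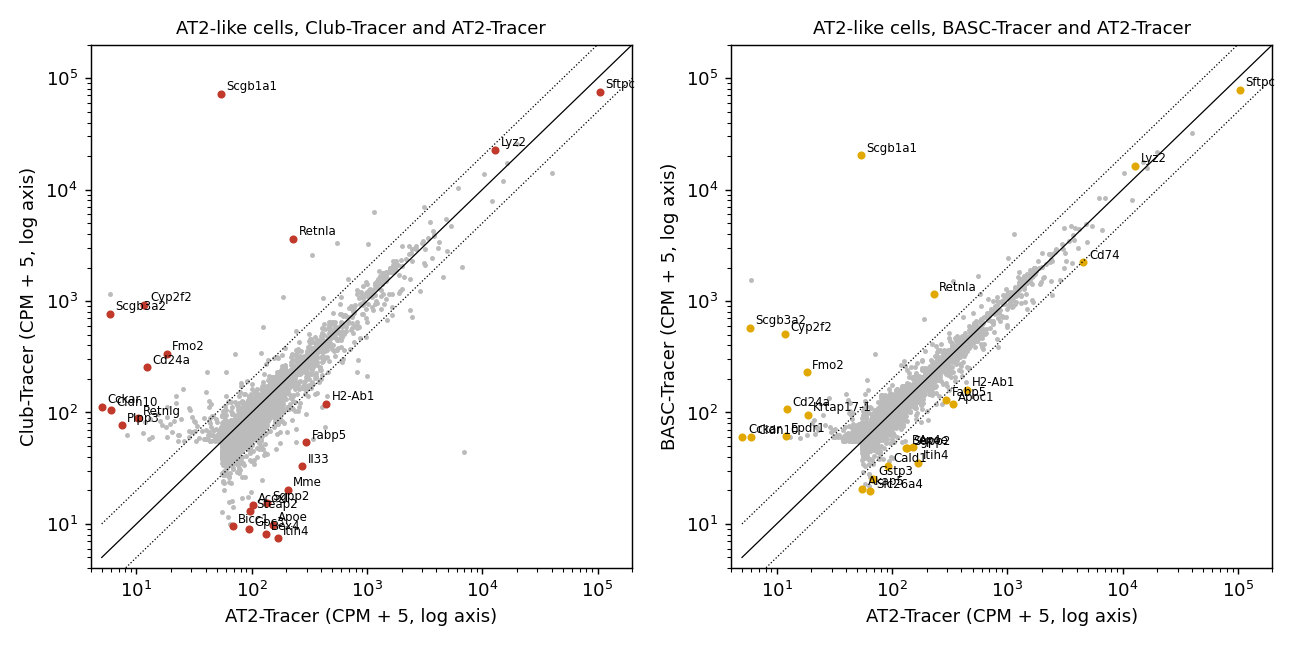
CPM + 5 of genes in AT2-like cells (log axes), Club-Tracer against AT2-Tracer on the left and BASC-Tracer against AT2-Tracer on the right, with grey points for genes at 50 CPM or more in either library, a solid line for equality and dotted lines for 2-fold. Named genes are coloured, among them Scgb1a1 at 72174 and 20393 CPM against 48.9 CPM in the AT2-Tracer library.

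AT2-like cells of the BASC-Tracer library, 251 in number (median 31156 UMIs), were compared with the same 1100 AT2-Tracer cells. The same club genes led the BASC-Tracer side. The median BASC-Tracer AT2-like cell held 39 UMIs of Scgb1a1, 0 of Scgb3a2, 5 of Cyp2f2 and 0 of Retnla, against 143.5, 4, 4 and 5 in the median endothelial-like cell of that library. The Scgb1a1, Scgb3a2 and Retnla levels of the median cell are therefore not read as expression, nor is that of Cyp2f2, which lay close to background. Scgb1a1 was 417-fold higher (391 to 445), Scgb3a2 641-fold (400 to 1102; 416-fold without the cell of each library with most of its UMIs, as 1 BASC-Tracer cell held 2090 of 4460), Cyp2f2 73.5-fold (61.7 to 88.3) and Fmo2 16.8-fold (14.8 to 19.3). Cckar was at 432 UMIs against 1 (ratio 1056, 188 to 41795). Cldn10 was 52.4-fold, Cd24a 13.8-fold, Epdr1 8.20-fold, Krtap17-1 6.67-fold and Retnla 5.11-fold higher. Fmo2, Cckar, Cldn10, Cd24a, Epdr1 and Krtap17-1 were not set against the background of endothelial-like cells. On the other side Itih4 was 5.40-fold higher (4.73 to 6.19) in AT2-Tracer cells, followed by the anion exchanger Slc26a4 (4.12-fold), Apoe (3.36-fold), Akap5 (3.21-fold), Sgpp2, Gstp3, Cald1, Bex4, the apolipoprotein Apoc1 (2.94-fold) and H2-Ab1 (2.85-fold). The median cell held 0 (BASC-Tracer) and 1 (AT2-Tracer) UMIs of Apoe. Sftpc stood at 78823 against 104100 CPM.

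By list, club stood at 2.22 (percentile 100) with 8 of 11 members 2-fold higher in the BASC-Tracer cells, and Ces1d (0.49) and Gsta4 (0.70) within 2-fold. Xenobiotic metabolism stood at 1.09 (percentile 100) with 5 of 9 members 2-fold higher, Cyp2b10 at -0.51 and Por at 0.58. The limit of free RNA holds for the club and xenobiotic metabolism lists here as well. MHC class II stood at -1.12 (percentile 0) with all 6 members 2-fold lower, including H2-Eb1 (-1.21), Cd74, the invariant chain (-1.04), and H2-DMb1 (-1.03). The macrophage or monocyte list stood at -0.68 (percentile 0.155). AT1 stood at -0.56 (percentile 0), with Col4a4 (-1.27) and Akap5 (-1.42) 2-fold lower and Gprc5a at 0.21. AT2 stood at -0.14 with Fabp5 (-1.19) and Chil1 (-1.11) 2-fold lower, and Cxcl15 at 0.44. Notch stood at 0.60 (Hes1 0.73), immediate early and heat shock at 0.22 with Hspa1a (1.11) and Hspa1b (1.34) 2-fold higher, lipid synthesis at 0.21 (Insig1 0.63, Pcyt1a 0.50) and TGF-beta and YAP targets at -0.18 (Ccn1 -0.25, Thbs1 0.34). Acute phase and injury secretion stood at -0.06 (Il33 -1.21, Lrg1 -0.90, C3 0.17), transitional at -0.08 (Lgals3 -0.87, Nupr1 0.80), p53 targets at 0.12 (Ccng1 0.37, Mdm2 0.26) and lung transcription factors at 0.17 (Id2 -0.69, Cebpa 0.44).

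Of 2945 genes, 79 were at least 2-fold apart, 47 higher in the BASC-Tracer cells and 32 higher in the AT2-Tracer cells, and gene limits of 20 and 100 CPM gave 133 and 41. The BASC-Tracer class held 69.3% of its cells in cluster 0 and 30.7% in cluster 18. Within cluster 18 alone (77 and 1057 cells) 9 genes were apart, the club list stood at 0.79, xenobiotic metabolism at 0.14, AT1 at -0.10, AT2 at 0.03 and MHC class II at -0.41. There the BASC-Tracer to AT2-Tracer ratio was 22.3 for Scgb1a1, 10.4 for Scgb3a2, 9.29 for Cyp2f2 and 0.472 for Retnla. It was 1.19 for Il33, 1.02 for Chil1, 0.723 for Itih4 and 0.959 for Apoe. Il33, Chil1 and Itih4 are among the genes leading cluster 18, which was built from expression. Holding to that cluster selects cells on these genes, so their ratios there are not a separate test. Within cluster 0 alone MHC class II stood at -1.51, and the ratio at 0.954 for Apoe, 9.42 for Cyp2f2, 9.40 for Retnla, 0.189 for Itih4, 0.477 for Chil1 and 0.702 for Il33.

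AT2-like cells of the Club-Tracer and BASC-Tracer libraries were compared last. As whole classes they had the fewest genes apart. So they did within cluster 0, with 14 against 73 for BASC-Tracer against AT2-Tracer and 123 for Club-Tracer against AT2-Tracer. The counts of 73 and 123 rest on the same 43 AT2-Tracer cells, while that of 14 compares 388 with 174 cells. Scgb1a1 was 3.54-fold higher (3.52 to 3.56) in the Club-Tracer cells, Retnla 3.16-fold, Retnlg 2.85-fold (5.78-fold without the cell of each library with most of its UMIs), Cd24a 2.44-fold, Plpp3 2.38-fold and the surface antigen Ly6a 2.03-fold. Lyz1, a lysozyme, Gpx2, a glutathione peroxidase, Cp, the copper carrier ceruloplasmin, and Cckar were between 1.93-fold and 1.97-fold higher. On the BASC-Tracer side the peptidase Mme was 5.31-fold higher (4.45 to 6.35), the small heat shock gene Hspb8 4.29-fold, Il33 4.07-fold (3.56 to 4.67), complement Hc 2.83-fold, Lars2 2.68-fold, the cyclooxygenase Ptgs1 2.64-fold and Fabp5 2.55-fold. Entpd1, Snhg11 and Adam19 were 2.49-fold, 2.39-fold and 2.37-fold higher there. Lars2 was higher on the BASC-Tracer side in club-like and ciliated-like cells as well, so its ratio is not particular to AT2-like cells. Sftpc was near even, at 74994 and 78823 CPM.

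By list, club stood at 0.73 (percentile 100), xenobiotic metabolism at 0.39 (Cyp2f2 0.88, Aldh1a1 0.89, Gstm1 0.06) and transitional at 0.14 (Clu 0.87, Nupr1 0.59, Hbegf -0.67). Free RNA limits the club and xenobiotic metabolism lists in this comparison too. TGF-beta and YAP targets stood at -0.54 (percentile 0; Ccn1 -0.66, Col4a1 -0.61, Amotl2 -0.60), AT1 at -0.43 (Vegfa -0.69, Hopx 0.20), MHC class II at -0.41 (Cd74 -0.43, H2-Aa -0.39) and AT2 at -0.19 (Napsa 0.25, Lyz2 0.48). Lipid synthesis stood at -0.21 (Fasn -0.40), immediate early and heat shock at -0.14 (Fosb -0.43, Atf3 -0.42), p53 targets at -0.10 (Ccng1 -0.67), lung transcription factors at -0.07 (Etv5 -0.78, Foxa2 0.20) and Notch at -0.09 (Hes1 0.01). Of 2839 genes, 29 were at least 2-fold apart, 7 higher in the Club-Tracer and 22 higher in the BASC-Tracer cells. The median gene lay at -0.13, and scaling by the median ratio gave 27 genes split 15 to 12. Within cluster 0 alone (388 and 174 cells) 14 genes were apart, MHC class II stood at -0.04, AT1 at -0.16 and club at 0.45, and a pseudocount of 20 CPM or a limit of 100 CPM gave 15 and 17 genes.

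**Figure D4:**
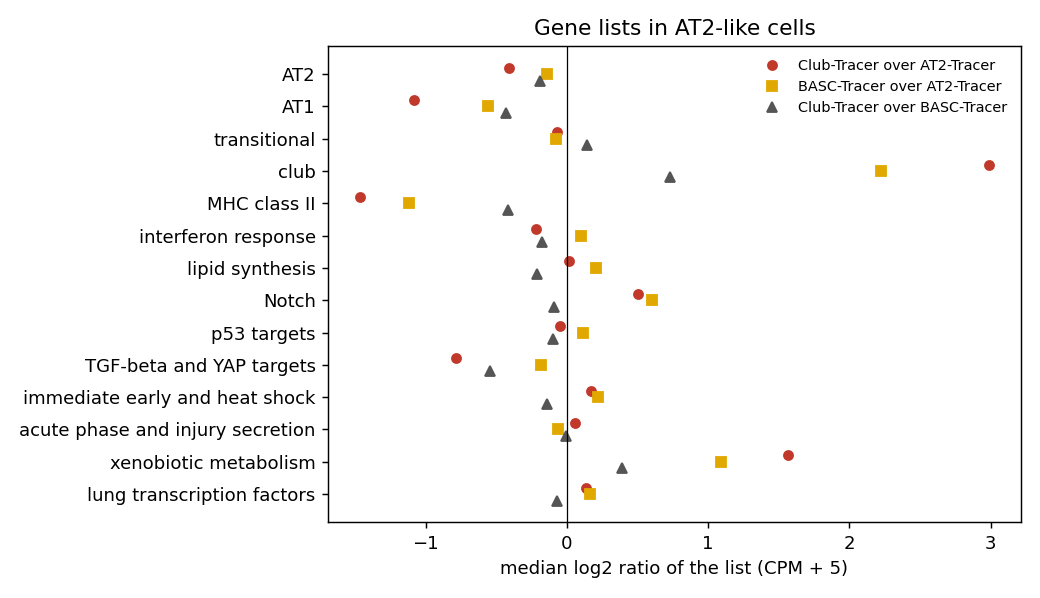
Median log2 ratio of fixed gene lists in AT2-like cells (log2 of CPM + 5 ratios) for Club-Tracer over AT2-Tracer, BASC-Tracer over AT2-Tracer and Club-Tracer over BASC-Tracer. The club list stood at 2.99, 2.22 and 0.73, and the MHC class II list at -1.47, -1.12 and -0.41.

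Other epithelial classes were compared where both libraries held 50 cells. In AT1-like cells, 110 BASC-Tracer against 939 AT2-Tracer, Scgb1a1 was 26.96-fold higher (24.5 to 29.7) on the BASC-Tracer side, at 1976 against 73.3 CPM, with Cyp2f2 at 19.1-fold. The median BASC-Tracer AT1-like cell held 8 UMIs of Scgb1a1 and 0 of Cyp2f2, as did the median macrophage or monocyte-like cell of that library, so these levels are not read as expression. The stress-induced cornified envelope gene Sprr1a (12.02-fold), Fam107b (4.65-fold) and haptoglobin Hp (3.44-fold) were higher on the BASC-Tracer side too. Of 465 Sprr1a UMIs there, 1 cell held 365, and without the cell of each library with most UMIs Sprr1a was 4.38-fold and Hp 2.21-fold higher. Chil3, a macrophage chitinase-like gene, was 15.9-fold higher (6.78 to 49.3) on the AT2-Tracer side, with Chil1 (7.72-fold), the lipocalin Lcn2 (4.81-fold), Apoe (3.34-fold) and Lyz2 (3.01-fold). Chil3 was seen in 34.8% of these AT2-Tracer cells and in 32.4% and 32.5% of the AT2-like and transitional-like ones, a level shared by these classes that is not read as expression. Nor are those of Apoe, with a median of 0 UMIs in both libraries, and Lyz2, with a median of 1 in both and 132 in AT2-Tracer macrophage or monocyte-like cells. Chil1 and Lcn2 had medians of 0 as well. Sftpc was 1.55-fold higher there, and 2.61-fold without the cell of each library with most of its UMIs. The median cell held 3 (BASC-Tracer) and 6 (AT2-Tracer) UMIs of Sftpc against means of 63.0 and 69.5, and macrophage or monocyte-like cells held medians of 2 and 4, so a few cells carry the Sftpc level. The MHC class II list stood at -1.10 and the macrophage or monocyte list at -1.02. Of 3806 genes 34 were apart, 17 on each side, and a pseudocount of 20 CPM gave 20 genes and doublets kept gave 57.

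In transitional-like cells, 56 Club-Tracer against 363 AT2-Tracer, Scgb1a1 was 276-fold higher (218 to 352) on the Club-Tracer side, with Cyp2f2 (43.1-fold), Slc38a1 (30.3-fold), the growth factor Mdk (27.1-fold) and the carbonyl reductase Cbr2 (24.4-fold). The median Club-Tracer transitional-like cell held 29 UMIs of Scgb1a1, 1 of Cyp2f2 and 2 of Cbr2, against 28, 1 and 2 in the median AT1-like cell, so these levels are not read as expression. Of 596 Cbr2 UMIs there, 1 cell held 384, and without the cell of each library with most UMIs Cbr2 was 10.01-fold and Cyp2f2 294-fold higher. Chil3 had 0 UMIs on the Club-Tracer side and was at least 23.8-fold higher on the AT2-Tracer side, against a floor of 3 counts. There 1 cell held 282 of its 453 UMIs and the median cell 0, the ratio without that cell was at least 9.03, and the level is not read as expression. Bex4 had 3 UMIs against 415 (ratio 21.8, 7.40 to 106), and Ptgs1 (19.6-fold), Egfl6 (9.91-fold) and Sftpc (6.99-fold) were higher on that side too, Egfl6 23.4-fold and Sftpc 22.2-fold without the cell of each library with most UMIs. The median cell held 2 (Club-Tracer) and 6 (AT2-Tracer) UMIs of Sftpc against a mean of 71.0 in the AT2-Tracer library, whose median macrophage or monocyte-like cell held 4, so a few cells carry the Sftpc ratio. The transitional list itself stood at 0.01, MHC class II at -1.58, macrophage or monocyte at -0.57 (percentile 0.64) and AT1 at -0.78. Of 3787 genes 141 were apart, 79 higher in the Club-Tracer and 62 higher in the AT2-Tracer cells.

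In club-like cells, 860 Club-Tracer against 168 BASC-Tracer, the secretoglobin Scgb3a1 (2.66-fold, or 7.10-fold without the cell of each library with most of its UMIs), the chemokine Cxcl2 (2.16-fold) and the acute phase gene Saa3 (2.15-fold) were higher on the Club-Tracer side, as were S100a6 and Krtap17-1 (1.58-fold and 1.55-fold). Sftpc was 3.36-fold higher (3.28 to 3.45) on the BASC-Tracer side, at 2099 against 624 CPM, but the median cell held 2 UMIs in both libraries and 1 BASC-Tracer cell held 3855 of 11008, so a few cells carry this ratio. Also higher there were Lars2 (2.59-fold), the amino acid transporter Slc6a14 (2.24-fold), the Ptp4a1 entry ENSMUSG00000117310 (1.97-fold) and AY036118 (1.92-fold). Scgb1a1 was near even, at 390121 against 331223 CPM. Of 1868 genes 12 were apart (2 and 10), with a median of -0.13 over all genes, and a pseudocount of 20 CPM gave 7.

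In ciliated-like cells, 477 Club-Tracer against 78 BASC-Tracer, the genes with the highest ratios on the Club-Tracer side were those of airway secretory cells. Bpifa1 was 78.9-fold higher (33.7 to 243), Scgb3a1 29.1-fold, Retnla 13.5-fold, Scgb3a2 10.2-fold and Scgb1a1 2.96-fold, and the antimicrobial lectin Reg3g was at 900 UMIs against 1 (ratio 198, 35.4 to 7818). The median Club-Tracer ciliated-like cell held 31 UMIs of Scgb1a1, 1 of Retnla and of Scgb3a2 and 0 of Bpifa1, Scgb3a1 and Reg3g. Of the Bpifa1 UMIs there, 1 cell held 1287 of 1795, and 1 cell held 2716 of 4110 Scgb3a1 UMIs. Without the cell of each library with most of its UMIs, Bpifa1 stood at 81.0 against 0 CPM. The median transitional-like cell of that library held 29 UMIs of Scgb1a1. Cluster 14, led by Scgb3a1, Bpifa1 and Reg3g, was larger in the Club-Tracer library, at 7.24% against 0.650% of cells, and these ratios are not read as expression by ciliated-like cells. The phosphate transporter Slc34a2 was 4.77-fold higher (3.50 to 6.51) on the BASC-Tracer side, or 2.92-fold without the cell of each library with most of its UMIs, with Tmem252 (3.38-fold), Eogt and Notch2 (each 2.11-fold) and Lars2 (2.03-fold). The ciliated list stood at 0.07. Of 3981 genes 23 were apart, 16 and 7.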

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

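The tests of the macrophage or monocyte-like cells below were chosen after their share had been seen. These cells made up 29.0% of the AT2-Tracer library, which was sorted for a label of Sftpc-expressing cells, and carried Chil3, Apoe and C1qb. Their ZsGFP level was 1.15% of that in AT2-like cells, which argues against a recombined reporter expressed in the macrophages themselves as the whole cause. The ratio of ZsGFP to Sftpc UMIs in these cells was 0.580 of that in epithelial clusters, so the few reporter UMIs may come from epithelial RNA. The sort on red alone held 0.257% such cells (1.38% with each library clustered alone), and green autofluorescence or engulfed reporter protein stays open because the sort gates and the lineage groups are the same samples. No other biological explanation was tested.

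The BASC-Tracer library held 7.58% macrophage or monocyte-like cells, with ZsGFP at 463 CPM, and 1 cell held 296 of the 528 ZsGFP UMIs. Without that cell the level was 207 CPM. Endothelial-like cells made up 11.1% of the BASC-Tracer library, with ZsGFP at 3017 CPM in cells of few UMIs. Endothelial-like cells made up 3.09% of the Club-Tracer library, with tdT at 482 CPM. ZsGFP stood at 26.5 CPM in the Club-Tracer library, which was sorted for red alone, and its source was not tested.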

How the results depend on the processing

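Each comparison rests on 1 library per lineage. Values moved with the filters, cluster settings and scaling, and the cause of each move was not tested. No paired analysis was possible because the labels do not pair the libraries by animal. The looser naming rule, the subsets of AT2-like cells and the ratios without the cell of each library that held most UMIs of the gene were chosen after the data had been seen. Cluster 18 alone could not be compared for the Club-Tracer library, which held 7 such cells. Of the alternative values for shares, counts of genes and the 5 lists AT2, AT1, club, MHC class II and xenobiotic metabolism, 151 moved past the interval of the value or, for counts, by more than 1.5 times, and 140 did not. Of the ratios of single named genes that were at least 2-fold apart, 1 reversed within cluster 0 and 3 within cluster 18. Lrg1, Chil1 and Il33, which were among those that reversed, lead cluster 18, so the split into clusters itself can set this. Smaller ratios crossed 1 as well, among them H2-Ab1 (0.740 to 1.10) and Lrg1 (0.798 to 1.09) within cluster 0, Club-Tracer against BASC-Tracer. Without the cell with most UMIs of the gene, 45 of the ratios moved past their interval, 194 did not and 0 of those at least 2-fold apart reversed.

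Shares of kept cells in a class moved under these settings. A mitochondrial limit of 10% gave AT2-like 15.4% (Club-Tracer) and 16.8% (AT2-Tracer), AT1-like 2.94% (Club-Tracer) and 14.9% (AT2-Tracer), transitional-like 2.47% (Club-Tracer), 6.92% (BASC-Tracer) and 12.4% (AT2-Tracer), club-like 39.3% (Club-Tracer) and 16.4% (BASC-Tracer), ciliated-like 13.7% (Club-Tracer). A mitochondrial limit of 25% gave AT2-like 10.9% (Club-Tracer), 14.9% (BASC-Tracer) and 14.3% (AT2-Tracer), AT1-like 6.63% (Club-Tracer), 14.1% (BASC-Tracer) and 21.4% (AT2-Tracer), transitional-like 3.21% (Club-Tracer), 10.7% (BASC-Tracer) and 12.1% (AT2-Tracer), club-like 36.2% (Club-Tracer) and 17.5% (BASC-Tracer). At least 1000 genes per cell gave AT2-like 16.2% (Club-Tracer), 25.9% (BASC-Tracer) and 26.1% (AT2-Tracer), transitional-like 3.48% (Club-Tracer), 14.8% (BASC-Tracer) and 17.7% (AT2-Tracer), AT1-like 12.6% (AT2-Tracer). Doublets kept gave AT2-like 9.01% (Club-Tracer), 15.3% (BASC-Tracer) and 17.7% (AT2-Tracer), club-like 35.9% (Club-Tracer) and 17.5% (BASC-Tracer), AT1-like 14.6% (AT2-Tracer), transitional-like 7.41% (AT2-Tracer). Resolution 0.5 gave AT1-like 6.27% (Club-Tracer), 12.6% (BASC-Tracer) and 18.5% (AT2-Tracer), transitional-like 3.63% (Club-Tracer), 16.8% (BASC-Tracer) and 21.99% (AT2-Tracer), club-like 32.4% (Club-Tracer) and 15.6% (BASC-Tracer). Resolution 2 gave transitional-like 2.70% (Club-Tracer), 9.89% (BASC-Tracer) and 13.6% (AT2-Tracer), AT2-like 21.0% (AT2-Tracer). Each library clustered alone gave AT2-like 15.1% (Club-Tracer), 14.2% (BASC-Tracer) and 15.3% (AT2-Tracer), AT1-like 6.95% (Club-Tracer) and 4.91% (BASC-Tracer), transitional-like 4.76% (Club-Tracer) and 8.60% (AT2-Tracer), club-like 24.7% (Club-Tracer), 18.2% (BASC-Tracer) and 8.13% (AT2-Tracer), ciliated-like 17.7% (Club-Tracer). The looser naming rule gave transitional-like 11.9% (Club-Tracer), 18.6% (BASC-Tracer) and 17.7% (AT2-Tracer), club-like 34.9% (Club-Tracer).

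Thinned to 3000 UMIs, the shares of Club-Tracer, BASC-Tracer and AT2-Tracer cells with a UMI were 51.1%, 65.9% and 84.8% for Sftpc, 99.3%, 85.05% and 8.01% for Scgb1a1, 50.3%, 64.2% and 61.8% for Ager, 73.9%, 66.9% and 53.5% for Krt8, 50.7%, 55.4% and 7.15% for Sftpc and Scgb1a1. Without thinning, the shares of Club-Tracer, BASC-Tracer and AT2-Tracer cells with a UMI were 85.3%, 90.8% and 98.3% for Sftpc, 100.0%, 99.4% and 20.6% for Scgb1a1, 67.4%, 76.9% and 71.1% for Ager, 87.4%, 79.1% and 62.3% for Krt8, 85.3%, 90.4% and 20.4% for Sftpc and Scgb1a1.

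In AT2-like cells, Club-Tracer against AT2-Tracer, the counts of genes and medians of lists (log2) moved. A pseudocount of 1 CPM gave club 4.24, MHC class II -1.58 and xenobiotic metabolism 1.70. A pseudocount of 20 CPM gave AT1 -0.91, club 1.73, MHC class II -1.35 and xenobiotic metabolism 1.17. A limit of 20 CPM gave 339 genes apart. A limit of 100 CPM gave 113 genes apart. Scaling by the median ratio gave AT2 -0.27, AT1 -0.94 and MHC class II -1.32. The mean over cells of CPM gave AT2 -0.36, AT1 -1.12 and MHC class II -1.44. Cluster 0 alone gave 123 genes apart, AT2 -0.14, AT1 -0.37, club 2.82, xenobiotic metabolism 1.03 and a ratio of 1.01 for Lrg1, reversed.

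In AT2-like cells, BASC-Tracer against AT2-Tracer, the counts of genes and medians of lists (log2) moved. A pseudocount of 1 CPM gave club 2.80 and xenobiotic metabolism 1.48. A pseudocount of 20 CPM gave club 1.80, MHC class II -1.03 and xenobiotic metabolism 0.88. A limit of 20 CPM gave 133 genes apart. A limit of 100 CPM gave 41 genes apart. The mean over cells of CPM gave AT1 -0.48 and MHC class II -0.98. Cluster 0 alone gave AT2 -0.030, AT1 -0.37 and MHC class II -1.51. Cluster 18 alone gave 9 genes apart, AT2 0.030, AT1 -0.10, club 0.79, MHC class II -0.41, xenobiotic metabolism 0.14, a ratio of 0.472 for Retnla, reversed, a ratio of 1.02 for Chil1, reversed and a ratio of 1.19 for Il33, reversed. Cells with 10000 UMIs or more gave AT2 -0.094.

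In AT2-like cells, Club-Tracer against BASC-Tracer, the counts of genes and medians of lists (log2) moved. A pseudocount of 20 CPM gave 15 genes apart, AT1 -0.34 and club 0.56. A limit of 20 CPM gave 53 genes apart. A limit of 100 CPM gave 17 genes apart. Scaling by the median ratio gave AT2 -0.049, AT1 -0.30, club 0.86 and MHC class II -0.29. The mean over cells of CPM gave club 0.81 and MHC class II -0.46. Cluster 0 alone gave 14 genes apart, AT2 -0.10, AT1 -0.16, club 0.45, MHC class II -0.040 and xenobiotic metabolism 0.27.

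Outside AT2-like cells, the count of genes apart moved for AT1-like cells, BASC-Tracer against AT2-Tracer, to 20 with a pseudocount of 20 CPM and to 57 with doublets kept, and for club-like cells, Club-Tracer against BASC-Tracer, to 7 with a pseudocount of 20 CPM.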

Other observations

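Cluster 17, an unnamed cluster that carried Sftpc, was led by Sprr1a, Cdkn1a, Ccng1 and Phlda3. It expressed the cell cycle inhibitor Cdkn1a at 2651, 2649.7 and 2538 CPM in the Club-Tracer, BASC-Tracer and AT2-Tracer libraries, against 328, 397 and 429 CPM in cluster 0. Ccng1 stood at 599, 912 and 735 CPM, Phlda3 at 628, 379 and 454 CPM, Gdf15 at 440.4, 267 and 444 CPM, and Mdm2 at 291, 261 and 242 CPM. Sftpc stood at 26262, 25077 and 39048 CPM. Of the members of the p53 target list at 50 CPM or more, 12 of 13, 11 of 12 and 11 of 12 were 2-fold higher in cluster 17 than in cluster 0 of the same library. Against cluster 13, the transitional-like cells, only 3 of 13, 1 of 12 and 2 of 12 were, and Cdkn1a there stood at 1035, 1330.4 and 1206 CPM. The cluster was described by its leading genes, so the levels are not a test.

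Unnamed cells of the Club-Tracer library included 2 groups described here. Cluster 14, an airway secretory group, expressed Scgb3a1 at 40571 CPM, the antimicrobial Bpifa1 at 7853 CPM and the gel-forming mucin Muc5b at 487 CPM beside Scgb1a1 at 192207 CPM. Cluster 10 expressed the chitinase Chia1 at 2166 CPM, Ly6a at 1993 CPM and the keratin Krt7 at 1914 CPM, with Scgb1a1 at 54401 CPM, below the 72174 CPM of AT2-like cells, and it is described by these genes alone. Macrophages also parted into groups: cluster 20 was led by Chil3, Ear2 and Marco, cluster 22 by Apoe, C1qb and Mmp12, and cluster 23 by Ccl8, Cxcl13 and Cd163.

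Of the tests of 2 patterns in AT2-like cells below, those of free Scgb1a1 RNA, doublets, MHC class II in the class with the lowest median, and different clusters were chosen after the results were seen. The others, on the club profile, on macrophage RNA as the source of Apoe and on MHC class II in AT1-like cells, were set before.

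Scgb1a1 was high in AT2-like cells of the Club-Tracer and BASC-Tracer libraries. Of Club-Tracer AT2-like cells, 66.3% held more Scgb1a1 UMIs than 95% of transitional-like cells, past the bound of 50%. A share of 32.2% (27.6 to 37.0) held more than any of them (937 UMIs), where doublets at the expected share were put at under 25%. Against endothelial-like cells, whose highest held 610 UMIs, 38.0% (33.2 to 43.0) held more. But 46.6% (41.6 to 51.6) held more than 95% of them, an interval that spans the bound of 50%. The shares above the highest cell of either class passed the bound of 25%. That bound rests on an expected doublet share, taken because the automatic threshold marked too few barcodes, and not on a measured one. Doublets therefore stay open in the Club-Tracer library. They stay open in the BASC-Tracer library too, where 54.2% (47.8 to 60.5) held more than 95% of transitional-like cells. A share of 29.5% (23.9 to 35.5) held more than any of them. These intervals span the bounds of 50% and 25%. Against endothelial-like cells, 27.1% (21.7 to 33.0) held more than 95% of them and 23.9% more than any. The bound of 25% was the same as for the Club-Tracer library, where 89 barcodes were marked as doublets. Only 17 were marked in the BASC-Tracer library, so the expected share would put the bound lower there. Both counts were set by that expected share and do not measure doublets. Of the same BASC-Tracer AT2-like cells, 11.2% (7.54 to 15.7) held more than any AT1-like cell, and 2.39% more than any macrophage or monocyte-like cell. The question is therefore not decided. Free RNA stays open because it did not reach other cells alike: transitional-like cells held at most 2.98% of the mean UMIs per AT2-like cell, but endothelial-like cells held 12.4% (Club-Tracer) and 23.9% (BASC-Tracer), between the bounds of 10% and 50%. AT2-like cells held a mean of 1896 and a median of 346 UMIs in the Club-Tracer library, and 635 and 39 in the BASC-Tracer library, the last below the endothelial-like median of 143.5. A club cell profile added to AT2-like cells stays open: 8 other club genes reached a median of 80.0% of the Scgb1a1 share of the club-like level, past the bound of 50%, but their quartiles were 47.7% and 137%, 3 genes lay under 50%, and the gene limits were not part of that prediction. Descent from Scgb1a1-expressing cells, the difference the design names, was not tested and may apply too.

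Apoe and MHC class II genes were higher in AT2-like cells of the AT2-Tracer library. This was not particular to AT2-like cells. The MHC class II list was also lower in BASC-Tracer AT1-like and Club-Tracer transitional-like cells than in the same AT2-Tracer classes. All transitional-like cells lay in cluster 13, so that difference lay within a single cluster. The BASC-Tracer to AT2-Tracer ratio of Apoe in AT1-like cells was 0.299, at levels not read as expression. Macrophage RNA as the source of Apoe stays open: macrophage genes reached a median of 24.3% of the Apoe share of the macrophage level, between the bounds set, and the highest, Mpeg1, stood at 1.28% of its macrophage level against 0.744% for Apoe. For free RNA as the source of MHC class II, the test set before left it open, with AT1-like cells at 32.4% of the mean UMIs per AT2-like cell, while the test chosen afterwards argues against it as the whole cause, since macrophage or monocyte-like cells had a median of 5.59% of that of AT2-like cells. In that library free Sftpc RNA reached classes more alike, at medians of 6, 6 and 4 UMIs in AT1-like, transitional-like and macrophage or monocyte-like cells. For MHC class II, the Club-Tracer median stood at -1.51 within cluster 0, so the difference was also found inside that cluster. The reference there was 43 AT2-Tracer cells, 3.91% of that class, and cluster 18 held only 7 Club-Tracer cells. The BASC-Tracer median stood at -1.51 within cluster 0, against the same 43 cells, and at -0.41 within cluster 18. Different clusters therefore stay open for MHC class II in both libraries. For Apoe different clusters stay open: the Club-Tracer to AT2-Tracer ratio was 0.331 (0.185 to 0.623) within cluster 0. The BASC-Tracer to AT2-Tracer ratio was 0.954 (0.555 to 1.74) within cluster 0 and 0.959 (0.841 to 1.09) within cluster 18, so that difference went with the clusters. Lineage of origin was not tested and stays open.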
